A study of Mus musculus with 24 samples.

How the data were processed

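Sorted colon fibroblasts from mice were profiled on 24 Affymetrix GeneChip Mouse Transcriptome Array 1.0 arrays, 1 array per sample. The cells lay in the gate Epcam-negative, CD45-negative, CD31-negative and gp38-positive, gp38 being podoplanin, and came from mice with an inducible Cre recombinase under the Villin promoter, which is active in the intestinal epithelium. Per the labels, total RNA was extracted with Agencourt RNAdvance Cell v2 including a DNase step, its quality was checked on a BioAnalyzer, and a small amount was amplified with the 3' IVT pico kit before hybridization. The 3 groups were WT with 7 arrays, ApcKO with 8 and IhhKO_ApcKO with 9. The labels do not state that each array came from a separate mouse, so every p-value below measures the spread between these samples. Arrays carry a sample code of a letter and a digit, and the replicates of different groups share no code that would pair them.

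The deposited values are log2 values that the authors made with RMA, the usual background correction, quantile normalization and summary per probe set. The RMA software, its version and the genome build are not given in the sources used here, so no positions are printed. The table held 72688 probe sets in 24 columns, and 0 columns were left without a sample. After 6732 control probe sets were left out, 65956 transcript clusters remained. Of these, 31388 had 1 gene symbol in the platform annotation, 1362 had several genes and were not named, and 33206 had no gene name here. Symbols were updated through the Entrez identifier for 853 probe sets. The probe set with the highest mean over all arrays stood for each of the 423 genes with more than 1, which gave 30827 genes, 19239 of them with a protein-coding RefSeq entry. No filter on dim genes was applied.

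Arrays give no counts, and their number limits the precision. Array medians over all transcript clusters lay between 4.96 and 5.14 log2 units, single values between 1.19 and 13.71, and the median gene at 5.605. The 5222 negative control probe sets had a median of 4.596 and a 95th percentile of 8.087. Antigenomic background probe sets, another control set, had lower array medians, from 2.68 on WT A1 to 3.15 on IhhKO_ApcKO C9. Whether a dim gene lies above background therefore depends on the control set used. No 2 arrays were identical.

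Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) on the log2 values, with all 24 arrays in 1 model. The planned contrasts were ApcKO minus WT, IhhKO_ApcKO minus ApcKO and IhhKO_ApcKO minus WT. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 30827 genes of its contrast. A comparison of IhhKO_ApcKO with the mean of WT and ApcKO was added after the data were seen. In simulated data each gene was drawn independently around its mean with its residual spread. There, 100 genes were changed by 0.5 log2 units and 100 others by 1. Of those changed by 0.5, the test recovered 89% for ApcKO minus WT, 88% for IhhKO_ApcKO minus ApcKO and 85% for IhhKO_ApcKO minus WT. Of those changed by 1, it recovered 100%, 100% and 98% in the same order. Beside both sets it called 9, 12 and 9 unchanged genes. So many changed genes make the Benjamini-Hochberg threshold less strict than it was in the real contrasts, where few genes passed. The shares recovered therefore do not measure power in the real data.

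The contrasts, tests, gene lists and rule for named genes were chosen before the data were examined. The 28 lists were Hedgehog target genes, Hedgehog receptors and mediators, BMP genes, Wnt ligands with R-spondins and secreted inhibitors, canonical Wnt targets, cytokines with chemokines and inflammatory mediators, interferon response genes, collagens and structural matrix, matrix-remodelling proteases and inhibitors, myofibroblast and smooth muscle contractile genes, TGF-beta genes, subepithelial PDGFRA-high fibroblast genes, CD34-positive crypt-base and adventitial fibroblast genes, general fibroblast genes, cell cycle genes, hypoxia and glycolysis genes, immediate early and stress genes, and markers of epithelium, leukocytes, blood endothelium, lymphatic endothelium, enteric glia and neurons, interstitial cells of Cajal, mesothelium, pericytes and erythroid cells, the female-linked gene Xist and Y-linked genes. For each list the mean of its measured members was taken per array, and the difference of group means was tested with an exact two-sided permutation test over all regroupings of the arrays of both groups, adjusted over the 28 lists of the contrast. Members were also counted over all genes and adjusted over the list alone. The lists were not chosen on these samples. A simulated shift of 0.3 in 1 list was recovered in each contrast, and with no shift 0 lists were called. The simulated genes were drawn independently, in 1 draw per contrast. It therefore does not measure power or false calls for real lists, whose members vary together.

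Named genes were the 8 genes per direction with the largest change among those past the threshold, without predicted or non-coding style symbols; where none passed, the 3 with the smallest p per direction; every measured Hedgehog target; up to 4 members with the smallest p of each other list described; and Ihh and Apc. Any other gene is said to be chosen after its values were seen. Relations between contrasts were computed across genes, beside 100 draws of simulated unchanged groups and 100 random splits of the shared group. The number of genes called was also counted in 100 splits of the arrays.

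The alternatives tried were quantile normalization of the deposited values, centring each array on its median, only the upper part of genes by mean, all probe sets, the mean of all probe sets of a gene, eBayes with trend and robust, array weights, only the groups compared, a minimum change of 1.5-fold, the epithelial marker mean, the leukocyte marker mean or the Xist level as a covariate, the code letter as a block, and leaving out each array in turn. For lists they were also the median over the members, camera with an estimated correlation and with the preset correlation of 0.01, and fry for change in either direction. Chosen after seeing the data were leaving out A1 and A8, A9 and B9, or A1, A8, B9 and C9, and the code letter as a block for single genes and lists. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.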

Results

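RNA levels were measured on 24 arrays of colon fibroblasts, 7 from WT mice, 8 from ApcKO mice and 9 from IhhKO_ApcKO mice, in which both genes were deleted. Apc restrains Wnt signalling, and Indian hedgehog (Ihh) is a secreted Hedgehog ligand of the colon epithelium. Because the Cre recombinase of these mice is active in the epithelium, levels of Ihh and Apc in the fibroblasts do not test the deletion. Values are RMA log2 values, given as group means with the SD, and differences are given in log2 units with the standard error (SE) of the limma model. The letter of the sample code ran almost along with genotype: WT arrays carried A, ApcKO arrays B except A9, and IhhKO_ApcKO arrays C except B9.

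The first comparison, ApcKO minus WT, asked what epithelial Apc loss did to the fibroblasts. No gene passed the test between 8 ApcKO and 7 WT arrays. The Hedgehog target genes were among those that did not pass. Gli1, the transcription factor that Hedgehog signalling switches on, was at 8.22 ± 0.14 (SD, n = 8) in ApcKO and 8.09 ± 0.08 (SD, n = 7) in WT. Interferon response genes had a lower mean in ApcKO by 0.29 log2 units, with 21 of 21 measured members lower, but this did not pass after adjustment over the lists. Epithelial markers averaged 0.51 log2 units more in ApcKO than in WT, within a wide spread between arrays.

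The limma test called 0 of 30827 genes for ApcKO minus WT, with 1360 genes at an unadjusted p under 0.05 where 1541 were expected by chance. The count was also 0 under all alternatives except the code letter as a block, which called 113 genes and compares A9 alone, the 1 ApcKO array with the letter A, with the WT arrays. Atoh8, a basic helix-loop-helix transcription factor, had the smallest p, with a log2 difference of -0.31 (SE 0.057, adjusted p = 0.47, lower than the WT mean in 8 of 8 ApcKO arrays). Il13ra2, the decoy receptor for interleukin-13, and Tmigd1, a membrane protein of the immunoglobulin family, had log2 differences of -1.45 (SE 0.34) and -0.96 (SE 0.22), with an adjusted p of 0.97 for both. Among genes with higher values in ApcKO, the smallest p values belonged to Tlk1, a kinase of chromatin assembly, at 0.23 (SE 0.051), to Thumpd3 at 0.26 (SE 0.061) and to Erg28 at 0.24 (SE 0.063), and none passed (adjusted p = 0.97 for each).

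Of the 7 measured Hedgehog target genes, 0 passed in ApcKO minus WT over all genes and 0 adjusted over the list alone. Besides Gli1 (log2 difference 0.14, SE 0.13), they were the receptor Ptch1 at 0.045 (SE 0.19), the Hedgehog-binding protein Hhip at 0.24 (SE 0.22), the forkhead factors Foxf1 at 0.073 (SE 0.066), Foxf2 at -0.073 (SE 0.10) and Foxl1 at 0.045 (SE 0.076), and the ligand Bmp4 at 0.028 (SE 0.12). Gli1 lay above the WT mean in 7 of 8 ApcKO arrays and above every WT array in 4. Its SE pools the spread of all 3 groups, of which IhhKO_ApcKO had the largest SD, 0.42. The mean of the Hedgehog target list differed by 0.071 (adjusted exact permutation p = 0.71). A missing call does not show that the levels were equal. Ihh and Apc differed by -0.070 (SE 0.069) and -0.060 (SE 0.058).

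The interferon response list averaged 6.91 ± 0.07 (SD, n = 8) in ApcKO and 7.20 ± 0.23 (SD, n = 7) in WT, with an exact permutation p of 0.0048 before and 0.13 after adjustment over the 28 lists. Over all genes 0 of its members passed, and adjusted over the list alone 2 did, the guanylate-binding protein Gbp3 at -0.42 (SE 0.12) and the immunoproteasome subunit Psmb8 at -0.27 (SE 0.082). Gbp2 and the oligoadenylate synthetase-like Oasl2 were at -0.47 (SE 0.18) and -0.29 (SE 0.12). Without the WT array A6 the list passed, with a difference of -0.35 (adjusted exact permutation p = 0.0093), and over all 23 alternatives with the permutation test the adjusted exact permutation p ranged up to 0.52.

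None of the other lists passed in ApcKO minus WT. Adjusted over the list alone, the chemokine Ccl8 at -0.85 (SE 0.24) passed within the cytokine list. So did the BMP-responsive genes Id2 at -0.34 (SE 0.10) and Id3 at -0.25 (SE 0.075) within the BMP list. The Wnt-enhancing Rspo1 at -0.26 (SE 0.079) passed within the Wnt ligand list. By the same rule 1 member was lower in each of the CD34-positive fibroblast and lymphatic endothelial lists. Ptgs2, the inducible cyclooxygenase, was at -0.29 (SE 0.10) and did not pass. Cell cycle genes averaged 0.14 more in ApcKO (adjusted exact permutation p = 0.48, 14 of 17 members with a positive difference), with the mitotic kinases Plk1 at 0.30 (SE 0.093) and Cdk1 at 0.28 (SE 0.13). Contractile genes averaged 0.092 more (adjusted exact permutation p = 0.70), with smooth muscle actin, Acta2, at 0.29 (SE 0.15). The epithelial difference of 0.51 had an adjusted exact permutation p of 0.52, with Epcam at 0.90 (SE 0.47) and Krt8, a keratin, at 1.04 (SE 0.60).

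Epithelial markers varied widely between arrays despite the gate against Epcam, with a mean per array from 5.62 to 8.28, and the lower values lie within the range of the negative controls. The mean of the 16 epithelial markers was 6.88 ± 0.71 (SD, n = 7) in WT, 7.39 ± 0.72 (SD, n = 8) in ApcKO and 7.08 ± 0.84 (SD, n = 9) in IhhKO_ApcKO, so that arrays within a group differed more than the groups did. Leukocyte markers averaged 5.32, 5.35 and 5.43 in the same order. The sex of the mice was not given in the labels. Xist, the RNA of the inactive X chromosome, was under 5 on 3 WT, 5 ApcKO and 3 IhhKO_ApcKO arrays and over 10 on 2, 3 and 6, with 2 WT arrays, A1 and A8, between.

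The second comparison, IhhKO_ApcKO minus ApcKO, asked what loss of epithelial Ihh added to Apc loss. The core Hedgehog target genes fell in the fibroblasts: Gli1 (Entrez gene 14632) fell by 1.31 log2 units (SE 0.13), Ptch1 (19206) by 1.32 (SE 0.18) and Hhip (15245) by 1.39 (SE 0.21), which is 2.47-fold, 2.49-fold and 2.62-fold, in 9 IhhKO_ApcKO against 8 ApcKO arrays. Lepr (16847), the leptin receptor, fell by 1.44 (SE 0.23). Mmp10 (17384), a matrix metalloproteinase also called stromelysin 2, was the 1 gene that rose, by 1.13 (SE 0.19), from 4.80 ± 0.23 (SD, n = 8) to 5.93 ± 0.45 (SD, n = 9). Its ApcKO level lay close to the negative control median of 4.60, so the size of this rise is uncertain. By list means, interferon response genes and matrix proteases were higher and contractile genes lower in the double knockout. The interferon and contractile calls were lost without 8 and 9 of 17 single arrays, and each of these list calls was lost with the median over the members. The cytokine list was also higher, but its call was lost with an estimated correlation (adjusted p = 0.084) and without 13 of 17 single arrays.

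**Figure D1:**
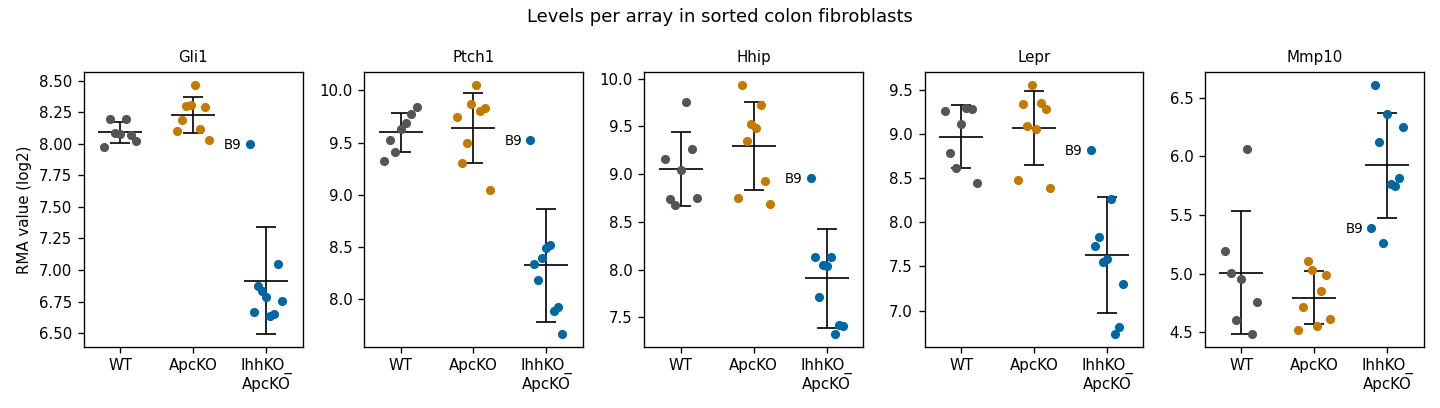
Each point is the RMA log2 value of 1 array for the gene named above the panel, by group (7 WT, 8 ApcKO and 9 IhhKO_ApcKO arrays); the horizontal mark is the group mean and the bars are 1 SD. For Gli1, 8 of the 9 IhhKO_ApcKO arrays lay between 6.64 and 7.05, and the array B9 was at 7.99.

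In this contrast 14 genes passed, 13 of them lower, with 1524 at an unadjusted p under 0.05 where 1541 were expected by chance. Gli1 averaged 8.22 ± 0.14 (SD, n = 8) in ApcKO and 6.92 ± 0.42 (SD, n = 9) in IhhKO_ApcKO (adjusted p = 4.03e-06), and all 9 double-knockout arrays lay below every ApcKO array. Ptch1 averaged 9.64 ± 0.33 and 8.33 ± 0.54 (adjusted p = 0.00139), Hhip 9.30 ± 0.46 and 7.91 ± 0.52 (adjusted p = 0.00459), and Lepr 9.07 ± 0.42 and 7.63 ± 0.66 (adjusted p = 0.00569). For these 3 genes 8 of the 9 IhhKO_ApcKO arrays lay below every ApcKO array. The array labelled IhhKO_ApcKO B9 stood apart, with Gli1 at 7.99, Ptch1 at 9.53 and Hhip at 8.96, within or near the range of the Ihh-intact arrays. Without B9 the count rose to 41 genes, among them all 14 of the full set, and the differences were -1.44 for Gli1, -1.47 for Ptch1, -1.52 for Hhip and -1.59 for Lepr.

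The other genes that fell by this rule were Cilp, a protein of cartilage matrix, by 0.74 (SE 0.14, adjusted p = 0.044), Ndst3, an enzyme of heparan sulfate synthesis, by 0.69 (SE 0.13, adjusted p = 0.033), Rbp4, a retinol carrier, by 0.67 (SE 0.12, adjusted p = 0.033), and Fancc, of the Fanconi anemia DNA repair complex, by 0.65 (SE 0.10, adjusted p = 0.0058). They lay below the ApcKO mean in 9, 9, 8 and 8 of the 9 double-knockout arrays. Cilp passed under 11 of 29 alternatives (adjusted p up to 0.14), Ndst3 under 16 (up to 0.094) and Rbp4 under 16 (up to 0.096). The remaining 5 were chosen after their values were seen. They were Gm16907 at -0.73, the phospholipid transfer protein Pltp at -0.54, the doublecortin-like kinase Dclk2 at -0.46, Thsd4, which binds microfibrils, at -0.42, and Eml1, a microtubule-binding protein, at -0.31, and of these Dclk2 passed under 12 of 29 alternatives, Thsd4 under 23 and Eml1 under 10. Mmp10 had an adjusted p of 0.0086 and was above every ApcKO array in 9 of 9. Gli1, Ptch1, Hhip, Lepr, Fancc, Mmp10, Gm16907 and Pltp passed under every alternative run on them except the code letter as a block. The 1.5-fold minimum was not among the alternatives run on single genes, and Pltp, at 1.45-fold, lies under it.

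The code letter leaves few arrays to separate it from genotype: only B9 shares a letter with ApcKO arrays. With the letter as a block, the count was 53 genes and shared 0 with the 14. The blocked difference was -0.25 for Gli1, -0.10 for Ptch1, -0.41 for Hhip, -0.33 for Lepr and 0.55 for Mmp10, and the signs of Rbp4 (0.073) and Fancc (0.032) turned. These estimates are B9 alone, the array with Ihh-intact levels of Gli1, minus the 7 ApcKO arrays with the letter B, so they do not show what the letter itself contributes. The count was 8 with median centring, 23 with the upper part of genes by mean and 65 with array weights. Leaving out single arrays gave 25 without A9, 9 without B4, 9 without B5, 9 without C1, 8 without C6 and 9 without C7.

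The mean of the 7 Hedgehog target genes fell by 0.66, from 8.87 ± 0.16 (SD, n = 8) to 8.21 ± 0.24 (SD, n = 9; adjusted exact permutation p = 0.0040), and was below the ApcKO mean in 9 of 9 arrays. All 7 members had a negative difference, 3 passed over all genes and 4 adjusted over the list alone. The fourth was Foxl1, a factor of subepithelial fibroblasts, at -0.37 (SE 0.072), which narrowly missed over all genes (adjusted p = 0.051). Foxf1 at -0.12 (SE 0.062), Foxf2 at -0.081 (SE 0.098) and Bmp4 at -0.010 (SE 0.12) did not pass. Ihh and Apc themselves were at 0.024 (SE 0.065) and -0.041 (SE 0.054).

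Hedgehog receptors and mediators averaged 0.083 lower (list difference -0.083, adjusted exact permutation p = 0.041), with 7 of 10 members negative, 0 past the threshold over all genes and 1 adjusted over the list alone. That 1 was Gli2, a transcription factor of the pathway, at -0.22 (SE 0.062), while the co-receptor Boc was at -0.19 (SE 0.088). This small shift depended on the processing, and with the median over the members it turned to 0.0085 (adjusted exact permutation p = 0.94, with a range from 0.024 over 25 alternatives).

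Matrix-remodelling proteases and inhibitors rose by 0.24 in the mean (adjusted exact permutation p = 0.0040), with 14 of 15 members positive and all 9 double-knockout arrays above the ApcKO mean. Besides Mmp10, the collagenase Mmp13 at 0.28 (SE 0.097), the stromelysin Mmp3 at 0.97 (SE 0.34) and the protease inhibitor Timp3 at 0.23 (SE 0.079) passed adjusted over the list alone, and 1 member, Mmp10, passed over all genes. Mmp13 averaged 3.75 in ApcKO and 4.02 in IhhKO_ApcKO, both under the negative control median of 4.60. Both lay above the antigenomic background medians, of which the highest was 3.15. Whether its difference lies above background therefore depends on the control set used. With the code letter as a block Mmp3 (-0.41) and Timp3 (-0.0019) changed sign. The call ended with the upper part of genes by mean (0.18, adjusted exact permutation p = 0.070) and with the median over the members (0.18, adjusted exact permutation p = 0.44).

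Contractile genes of myofibroblasts and smooth muscle fell by 0.27 in the mean, from 7.82 ± 0.12 (SD, n = 8) to 7.55 ± 0.21 (SD, n = 9; adjusted exact permutation p = 0.034), below the ApcKO mean in 9 of 9 arrays. Of the 14 members 13 were negative, 0 passed over all genes and 7 adjusted over the list alone. Among them were the myosin light chain Myl9 at -0.52 (SE 0.12), Acta2 at -0.56 (SE 0.14), the myosin kinase Mylk at -0.26 (SE 0.082) and the actin-binding Tagln at -0.37 (SE 0.13), of which Acta2 changed sign with the code letter as a block (0.046). The call ended without any 1 of the ApcKO arrays A9, B1, B2, B3, B4, B5 and B7 or of C3 and C9, with an adjusted exact permutation p of up to 0.087, with median centring (0.068) and with the median over the members (0.15).

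Interferon response genes rose by 0.30 in the mean, from 6.91 ± 0.07 (SD, n = 8) to 7.22 ± 0.26 (SD, n = 9; adjusted exact permutation p = 0.034), and were above the ApcKO mean in 8 of 9 arrays. Of 21 members 20 were positive, 0 passed over all genes and 9 adjusted over the list alone, among them Psmb8 at 0.29 (SE 0.077), the antiviral membrane protein Bst2 at 0.45 (SE 0.13), the oligoadenylate synthetase Oas2 at 0.58 (SE 0.18) and Oasl2 at 0.34 (SE 0.11). With the code letter as a block Psmb8 (-0.052), Bst2 (-0.062) and Oasl2 (-0.027) changed sign. The call ended without any 1 of A9, B1, B2, B3, B4, B5, B7 or C9, again with an adjusted exact permutation p of up to 0.087, and with the median over the members (0.077). The mean of the double knockout was close to that of WT, at 7.22 and 7.20.

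Cytokines, chemokines and inflammatory mediators rose by 0.16 in the mean (adjusted exact permutation p = 0.041), with 24 of 30 members positive and 9 of 9 arrays above the ApcKO mean, but 0 members passed over all genes and 0 adjusted over the list alone. The chemokine Cxcl5 was at 0.32 (SE 0.11), the acute-phase protein Saa3 at 1.04 (SE 0.35) and the B-cell chemokine Cxcl13 at 0.70 (SE 0.26). Without B9 they were at 0.26, 0.78 and 0.73 in the same order. With the code letter as a block, which rests on B9 alone, they were at 0.835, 3.04 and 0.37. With an estimated correlation the list had an adjusted p = 0.084, and it lost its call without most single arrays. Leukocyte markers, from cells that the gate against CD45 was set to remove, averaged 0.086 more in the double knockout (adjusted exact permutation p = 0.62), with Tyrobp at 0.34 (SE 0.17). With the leukocyte mean as a covariate the cytokine difference was 0.13 (95% interval 0.021 to 0.23).

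With camera and an estimated correlation the adjusted p was 0.00077 for Hedgehog target genes, 0.048 for their receptors and mediators, 0.048 for interferon response genes, 0.029 for proteases and 0.048 for contractile genes, so that these 5 lists kept their call and cytokines did not. With the code letter as a block, where B9 alone stands for the double knockout against the 7 ApcKO arrays with the letter B, the Hedgehog target list was at -0.12 (95% interval -0.46 to 0.21), interferon response genes at 0.030 (-0.43 to 0.49), proteases at 0.090 (-0.15 to 0.33), contractile genes at -0.027 (-0.43 to 0.37) and receptors and mediators at -0.053 (-0.18 to 0.073). Cytokines were at 0.40 (0.18 to 0.61). These values rest on 1 double-knockout array and do not separate genotype from the code letter, and the other 8 share no letter with another group. B9 lay within the range of the Ihh-intact arrays for Hedgehog targets, interferon response genes, proteases and contractile genes, but above all of them for cytokines (7.69, against at most 7.53). For the interferon, protease and contractile lists, lying within the range did not set B9 apart. Of the 9 double-knockout arrays, 2 lay above every WT array for interferon response genes and 3 for proteases. For contractile genes 3 lay below every WT array, while for Hedgehog targets 8 did.

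**Figure D2:**
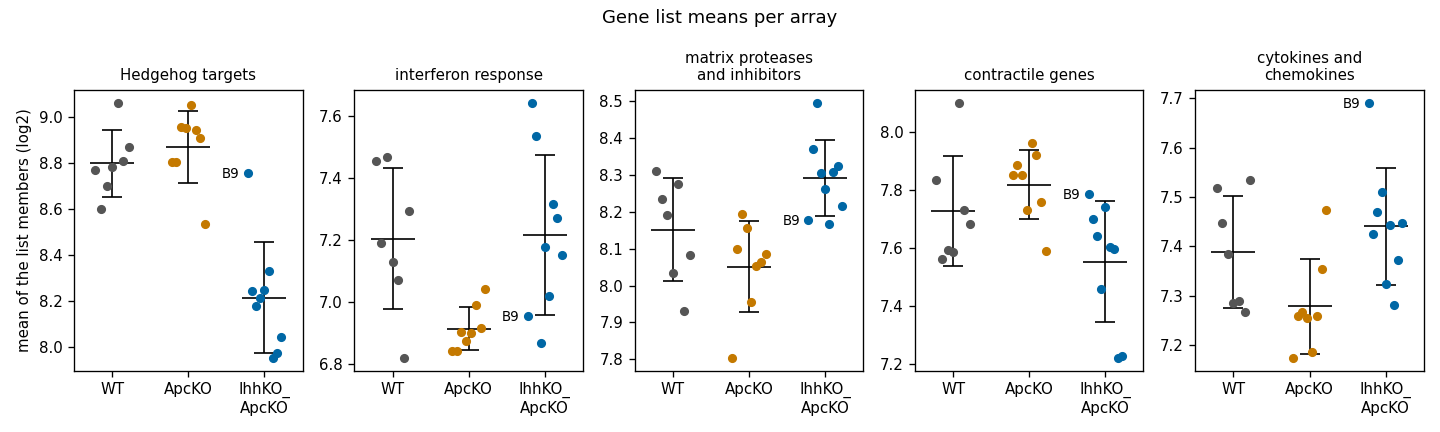
Each point is the mean log2 value of a list's measured members on 1 array, by group (7 WT, 8 ApcKO and 9 IhhKO_ApcKO arrays); the horizontal mark is the group mean and the bars are 1 SD. Hedgehog target genes averaged 8.80 in WT, 8.87 in ApcKO and 8.21 in IhhKO_ApcKO, and interferon response genes averaged 7.20, 6.91 and 7.22.

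The other 22 lists did not pass for IhhKO_ApcKO minus ApcKO, and the smallest adjusted exact permutation p among them was 0.48, for hypoxia and glycolysis genes with a mean difference of 0.075. Among signalling lists the mean differences were 0.0063 for BMP genes, 0.027 for Wnt ligands with R-spondins and inhibitors, 0.018 for canonical Wnt targets and -0.019 for TGF-beta genes. Rspo1 at 0.25 (SE 0.074) passed adjusted over the Wnt ligand list alone, and Sfrp1, a secreted Wnt inhibitor, at 0.30 (SE 0.10) did not. Collagens and structural matrix genes differed by -0.070, with 18 of 22 members negative, while the collagen crosslinking enzyme Lox at 0.33 (SE 0.083) and the fibril-associated collagen Col14a1 at -0.29 (SE 0.091) passed adjusted over the list alone. Subepithelial PDGFRA-high fibroblast genes differed by -0.079, with Foxl1 and endothelin-3, Edn3, at -0.22 (SE 0.076) lower and the growth factor Nrg1 at 0.69 (SE 0.16) higher adjusted over the list alone. CD34-positive fibroblast genes differed by 0.013 and general fibroblast genes by -0.048. Adjusted over the list alone, 1 CD34-positive fibroblast gene was higher and 1 blood endothelial marker lower.

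Cell cycle genes differed by 0.024 and immediate early genes by 0.031 in IhhKO_ApcKO minus ApcKO. Among markers of other cells, the differences were -0.31 for epithelium, with Epcam at -0.37 (SE 0.44), -0.0098 for blood endothelium, -0.060 for lymphatic endothelium, 0.0044 for enteric glia and neurons, -0.18 for interstitial cells of Cajal, 0.11 for mesothelium, -0.029 for pericytes and -0.020 for the 1 erythroid gene measured. Xist was higher by 1.84 and Y-linked genes were lower by 0.67 (difference -0.67), since more double-knockout arrays showed high Xist, and neither passed (adjusted exact permutation p = 0.62 for both).

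The third comparison, IhhKO_ApcKO minus WT, set the double knockout against mice with both genes intact. Ptch1 fell by 1.27 log2 units (SE 0.18), Gli1 by 1.17 (SE 0.13), Hhip by 1.15 (SE 0.21) and Lepr by 1.34 (SE 0.23), between 2.21-fold and 2.54-fold, in 9 IhhKO_ApcKO against 7 WT arrays. Nrg1 (211323), the growth factor neuregulin 1, rose by 0.90 (SE 0.17), from 7.37 ± 0.45 (SD, n = 7) to 8.27 ± 0.29 (SD, n = 9). The Hedgehog target list was the only 1 of the 28 lists to pass.

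For IhhKO_ApcKO minus WT 25 genes passed, 22 lower and 3 higher, with 2350 at an unadjusted p under 0.05 where 1541 were expected by chance. The adjusted p was 7.53e-05 for Gli1, 0.00315 for Ptch1, 0.030 for Hhip and 0.017 for Lepr, and 8 of 9 double-knockout arrays lay below every WT array for each, the exception being the array labelled B9. Tmigd1 fell by 1.19 (SE 0.22, adjusted p = 0.022), Ndst3 by 0.79 (SE 0.13, adjusted p = 0.013), Plppr5, a phospholipid phosphatase-related protein, by 0.77 (SE 0.13, adjusted p = 0.013) and Lrrtm3, a neuronal adhesion protein, by 0.65 (SE 0.13, adjusted p = 0.047). Eps8, a substrate of the epidermal growth factor receptor, rose by 0.39 (SE 0.077, adjusted p = 0.042), and the mitochondrial import protein Timm10 rose by 0.36 (SE 0.066, adjusted p = 0.022). Nrg1 had an adjusted p of 0.034 and was above the WT mean in 9 of 9 arrays, while its second, dim probe set differed by -0.0060. Ptch1, Gli1, Ndst3, Pltp and Gm16907 passed under all 28 alternatives other than the letter block, Plppr5 under 27, Lepr under 24, Tmigd1 under 20, Timm10 under 20, Nrg1 under 16, Hhip under 15, Eps8 under 9 and Lrrtm3 under 6.

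Of the lower genes 7 were shared with the comparison against ApcKO (Gli1, Gm16907, Hhip, Lepr, Ndst3, Pltp and Ptch1), where independent lists would share 0.0093, although both comparisons use the same double-knockout arrays. Pltp, at -0.64, and Gm16907, at -0.70, were chosen after their values were seen. Mmp10 was at 0.92 (SE 0.19), from a WT level of 5.01 close to the negative controls, and did not pass (adjusted p = 0.062). Without B9 the count was 67, among them all 25. It was 11 without A1 and A8, the WT arrays with both Xist and Y-linked signal, 16 without A1, 15 without A4, 12 without A5, 12 without A6, 15 without A8, 13 without C4, 15 without C6 and 16 without C7. With the code letter as a block it was 84 and shared 0 with the 25, and Gli1 was at -0.24 and Ptch1 at 0.044.

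The Hedgehog target list averaged 8.80 ± 0.14 (SD, n = 7) in WT and was lower by 0.58 in the double knockout (difference -0.58, adjusted exact permutation p = 0.017), with 6 of 7 members negative, 3 past the threshold over all genes and 4 adjusted over the list alone. With the code letter as a block it was at -0.12 (95% interval -0.60 to 0.36), an estimate that rests on A9 and B9. Foxl1 was at -0.32 (SE 0.074, adjusted p = 0.11), Foxf1 at -0.043 (SE 0.064), Foxf2 at -0.15 (SE 0.10) and Bmp4 at 0.018 (SE 0.12). Hedgehog receptors and mediators differed by -0.077 and did not pass (adjusted exact permutation p = 0.22), with Gli2 at -0.17 (SE 0.065) and the co-receptor Cdon at -0.36 (SE 0.12). Ihh and Apc were at -0.046 (SE 0.068) and -0.10 (SE 0.056).

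The lists that had moved against ApcKO were closer to WT. Interferon response genes differed by 0.011 (adjusted exact permutation p = 0.98), with Oas2 at 0.37 (SE 0.19) and Isg15, a ubiquitin-like protein, at 0.25 (SE 0.11). Cytokines differed by 0.051, with interleukin-1 beta, Il1b, at 0.61 (SE 0.18), a difference from a WT level of 4.56 that is not above the negative control median of 4.60. Matrix proteases differed by 0.14 (adjusted exact permutation p = 0.30) and contractile genes by -0.17 (adjusted exact permutation p = 0.46). Adjusted over the list alone, Lox at 0.38 (SE 0.086) passed among matrix genes, and Edn3 at -0.29 (SE 0.079) and Foxl1 among subepithelial fibroblast genes. Tek, an endothelial receptor, passed at -0.49 (SE 0.11) among blood endothelial markers. Among BMP genes the BMP pseudoreceptor Bambi at 0.36 (SE 0.10), Id2 at -0.30 (SE 0.099) and Id3 at -0.23 (SE 0.073) passed. Bambi was at -0.43 with the code letter as a block. By the same rule 1 member was higher in each of the protease, Wnt ligand and pericyte lists. In each of the general fibroblast, hypoxia and lymphatic endothelial lists 1 was lower.

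The comparison of IhhKO_ApcKO with the mean of WT and ApcKO, added after the data were seen, called 70 genes, 59 lower and 11 higher. The largest decreases were again in Lepr (-1.39), Ptch1 (-1.29), Hhip (-1.27) and Gli1 (-1.24, SE 0.11, adjusted p = 6.34e-07), followed by Fam162b (-0.75), Ndst3 (-0.74), the Notch-related Dner (-0.73) and the adhesion molecule Ncam1 (-0.68). Foxl1 fell by 0.35 (SE 0.062, adjusted p = 0.012). Mmp10 (1.02), Nrg1 (0.80), asparagine synthetase, Asns (0.41), Lox (0.35), matrix Gla protein, Mgp (0.35), Eps8 (0.34), the metallothionein Mt2 (0.32) and the chromatin remodelling subunit Baz1a (0.29) rose. The Ihh-intact levels of Mmp10 lay close to the negative controls, so the size of its rise is uncertain. Mgp was above the Ihh-intact mean in 8 of 9 arrays, Fam162b below it in 8 of 9, and B9 was the exception in both. Of 35 alternatives other than the letter block, Mt2 passed under 6, Baz1a under 11, Asns under 14 and Fam162b under 14. Dner passed under 22, Lox under 26, Ncam1 under 31 and Eps8 under 33, and the other named genes under all that were run on them. Among these others, Foxl1 (1.27-fold) and Mgp (1.28-fold) lie under the 1.5-fold minimum, which was not run on single genes. Without B9 the adjusted p of Mt2 was 0.057 (0.0085 to 0.17 over its alternatives). Without B9 the count was 119, sharing 66 with the 70, and with A1 and A8 left out it was 44. It was 45 without A6, 44 without C1, 44 without C3, 43 without C4, 43 without C6, 43 without C7 and 45 without C9, and 65 with 0 shared under the letter block.

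Across 30827 genes, which are not independent replicates, the changes ApcKO minus WT and IhhKO_ApcKO minus ApcKO had a Pearson r of -0.36. These contrasts share the ApcKO arrays, and simulated unchanged groups gave a mean r of -0.49. With the ApcKO arrays split so that none was shared, the mean r over 100 splits was 0.047. The changes of both Apc-deleted groups against WT had an r of 0.57, with 0.54 in simulated unchanged groups and 0.093 with the WT arrays split. No gene passed for ApcKO minus WT, so the overlap of called genes with that contrast was 0.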

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

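The tests of a mix of male and female material in A1 and A8 and of the sample code letter were chosen after the result was seen, as was the comparison with both Ihh-intact groups. Of 309 sets of values tested (28 lists and 75 genes in 3 groups), 18 held an array far from the others, where chance gives about 1 in 20, or 15.4, and 6 of the 18 concerned the array labelled IhhKO_ApcKO B9. The sets are not independent, since the Hedgehog target list itself holds Gli1, Ptch1 and Hhip. The counts are therefore not separate observations, and 15.4 is only a guide. For B9, the gap to the nearest array as a share of the range of its group was 0.529 for the Hedgehog target list, 0.699 for Gli1, 0.54 for Ptch1, 0.505 for Hhip, 0.598 for Fam162b and 0.554 for Mgp. B9 had a Hedgehog target mean of 8.75, against 7.95 to 8.33 on the other 8 arrays of its group. The values were 7.99 for Gli1 (others 6.64 to 7.05), 9.53 for Ptch1 (others 7.67 to 8.52), 8.96 for Hhip (others 7.33 to 8.14), 7.35 for Fam162b (others 6.11 to 6.61) and 11.61 for Mgp (others 11.96 to 12.25).

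A poor array was tested as a technical explanation of B9, on 115 genes called without it and outside the Hedgehog target list. On a scale from 0, the mean of its group, to 1, the Ihh-intact arrays, B9 had a median position of 0.818, and 87 of the 115 genes lay nearer to the Ihh-intact level. The same measure on the other 8 arrays, each placed on genes called without it, reached at most 0.48. Those arrays were placed on 39 to 55 genes called with B9 still in the group, so the comparison is not like for like. The array median of B9, 4.96, and its upper quartile, 6.43, were the lowest of all arrays. Its median correlation with the other arrays was 0.985. C9 had a lower correlation, 0.974, but a position of -0.273. The high position of B9 therefore does not exclude a generally poor array. A sample of an Ihh-intact mouse under the label of B9 may account for the position of 0.818. So may a mouse in which the deletion did not take place. These cannot be separated with the values here. The means of B9 for cytokines (7.69) and leukocyte markers (5.65) lay above all Ihh-intact arrays, and why was not tested. For leukocyte markers C7 (5.55) and C9 (5.72) also lay above them. The labelled grouping was kept, and the report gives the counts without B9.

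The interferon response list was higher in IhhKO_ApcKO than in ApcKO by 0.301, and 5 explanations were tested. Carried-over epithelium, which the gate against Epcam was set to remove, or a sex imbalance would each have lowered the difference once taken up as a covariate. It stayed at 0.308 and 0.262, with 95% intervals above 0. With the leukocyte mean as a covariate, for cells that the gate against CD45 was set to remove, it was 0.335, also with an interval above 0. That mean lay only between 5.16 and 5.72 on all arrays, near the negative control median of 4.596. Such a dim measure cannot exclude carried-over leukocytes. A single array is not the source, since the lowest difference without any 1 array was 0.248. With the code letter as a block the difference was 0.0302 (95% interval -0.43 to 0.49), but this is B9 alone minus the 7 ApcKO arrays with the letter B and decides nothing, since B9 may be an Ihh-intact sample. Loss of Ihh and a handling difference along the letters cannot be told apart, because the other 8 double-knockout arrays share no letter with another group. WT, with Ihh intact, averaged 7.20, close to the 7.22 of IhhKO_ApcKO, against 6.91 in ApcKO. The difference may therefore lie in low values of the ApcKO arrays, which was not tested.

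On the WT arrays A1 and A8, Xist was at 7.15 and 9.50, together with a Y-linked mean of 6.38 and 6.28. The 11 arrays with low Xist had a Y-linked mean of 6.35 (SD 0.241) and the 11 with high Xist 4.10 (SD 0.0528). Mixed male and female material, a candidate explanation, would put the Y-linked mean of A8 at 5.96 from its Xist share of 31.3%, and the measured value deviated by 0.33, inside 2 SD (0.482) of the low-Xist arrays. The predicted drop of 0.39 also lies inside 2 SD, so this test could not decide, and no biological explanation was tested.

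Chance splits of the arrays were counted beside the real ones, 100 in each comparison with the real one included. For ApcKO minus WT, where 0 genes passed, each of the 100 splits gives at least as many by construction (highest other 0), so the count of splits says nothing about chance there. For IhhKO_ApcKO minus ApcKO 2 of 100 splits gave at least the real 14 genes, and the highest other gave 27, more than the real groups, of which 0 were among the 14. In that split 6 of the 9 arrays on the side with B9 and 2 of the 8 on the other had low Xist, 0 of its 27 genes were among the sex-linked genes listed, and why this split called genes was not tested. For IhhKO_ApcKO minus WT the real 25 was reached by 1 of 100 splits, itself, and the highest other gave 11. The added comparison had 70 genes, reached by 1 split, itself, with 34 as the highest other. The share of splits was under 0.05 for these 3 counts, so counts this high were rare among random groupings. Chance is not excluded by this, since a random split called 27 genes against the real 14. The splits also say nothing about structure that runs along with genotype, such as the code letter, for any of the 3. Nor do they account for the choice of the added comparison after the data were seen.

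The other sets with an array far from the rest are given as values of the same share. Blood endothelial markers were highest on IhhKO_ApcKO C9 (0.665), which also had the lowest Gli2 (0.593) and the lowest median correlation with the other arrays, 0.974. In ApcKO, Thumpd3 (0.644) and Lrrtm3 (0.541) were lowest on B4, Gbp2 highest on B5 (0.556), Sfrp1 lowest on A9 (0.591) and Mt2 highest on B8 (0.555). In WT, Bmp4 was lowest on A2 (0.656), Mylk (0.645) and Baz1a (0.637) highest on A5 and Dner lowest on A4 (0.61). Baz1a was also highest on IhhKO_ApcKO C3 (0.54).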

How the results depend on the processing

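Chosen after seeing the data were the added comparison, leaving out A1 and A8, A9 and B9 or A1, A8, B9 and C9, and the letter block for single genes and lists. The counts of genes below are for IhhKO_ApcKO minus ApcKO, minus WT and minus both Ihh-intact groups, against 14, 25 and 70; each is given where it moved by over 1.5 times, and the cause was not tested unless stated. Median centring gave 8, 16 and 34, array weights 65, 45 and 119, and leaving out A9 and B9 39, 72 and 112. The upper part of genes by mean, where fewer genes were tested, gave 23 against ApcKO; leaving out A1, A8, B9 and C9 gave 28 there. Against WT, only the groups compared gave 7, leaving out A1 and A8 gave 11, and a 1.5-fold minimum, which removes smaller changes, gave 16. Against both groups the 1.5-fold minimum gave 18, the Xist covariate 46 and leaving out A1 and A8 44. The letter block gave 53 and 84, and 113 for ApcKO minus WT, where all other alternatives gave 0. Without 1 array the counts ranged from 8 to 41, 12 to 67 and 43 to 119, the highest without B9, and were 0 to 0 for ApcKO minus WT. The letter block also turned Rbp4 to 0.0731 and Fancc to 0.0316 against ApcKO, Ptch1 to 0.0438, Ndst3 to 0.3644 and Lrrtm3 to 0.049 against WT, and Fam162b to 0.2019, Ndst3 to 0.0596 and Mgp to -0.0154 against both. Among genes that had passed only adjusted over the list alone it turned Mmp3 (-0.405), Acta2 (0.0456), Psmb8 (-0.0517), Bst2 (-0.0622), Oasl2 (-0.0271) and Timp3 (-0.0019) against ApcKO and Bambi (-0.4345) against WT. The block rests on B9 alone against ApcKO, on A9 alone for ApcKO minus WT and on both in the other comparisons, and so does not show what the letter contributes. The Hedgehog target list kept its direction and its call against ApcKO from -0.7228 to -0.6225 without 1 array and under each other alternative but the letter block, where it was at -0.12 with a 95% interval from -0.46 to 0.21. Against WT it ranged from -0.652 to -0.5407 without 1 array, its call ended with fry (adjusted p = 0.088), and with the letter block it was at -0.12 with a 95% interval from -0.60 to 0.36; for ApcKO minus WT it ranged from 0.03746 to 0.1187 and was never called. The other lists called against ApcKO lost their calls under some alternatives. Hedgehog receptors gave -0.08118 with median centring, -0.08296 with the upper part of genes, 0.008528 with the median over members, -0.09262 without A9 and B9 and -0.07026 without A1, A8, B9 and C9, with an adjusted p = 0.964 by fry and a range from -0.09477 to -0.06746 without 1 array, where 15 of 17 ended the call. Cytokines gave 0.1634, 0.1698, 0.1704, 0.1155 and 0.1251 under the same settings, an adjusted p = 0.0835 by camera with an estimated correlation and 0.0934 by fry, and a range from 0.1304 to 0.1894, where 13 of 17 ended the call. Interferon genes gave 0.2637 with the median over members and a range from 0.2476 to 0.3443 (8 of 17). Proteases gave 0.1785 with the upper part of genes, 0.1807 with the median and a range from 0.2047 to 0.2606, all called. Contractile genes gave -0.2647 with median centring, -0.2926 with the median, an adjusted p = 0.12 by fry and a range from -0.2991 to -0.225 (9 of 17). With the preset correlation camera called 4, 11 and 8 of 26 lists in ApcKO minus WT, IhhKO_ApcKO minus ApcKO and IhhKO_ApcKO minus WT, and with an estimated correlation 0, 5 and 1. The r of the first relation across genes turned to 0.04746 and that of the second moved to 0.09294 once no array was shared, so the shared arrays account for most of both. Genes near the negative control median of 4.596 are limited by signal over background.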

Other observations

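All tests in this part belong to the comparison added after the data were seen, and all its genes were chosen after their values were seen. Several genes outside the fixed lists fell in it against the mean of WT and ApcKO. They were picked singly, with no list or enrichment behind them, and include asporin, Aspn, at -0.63 (SE 0.14, adjusted p = 0.048), Igsf10 at -0.63 (SE 0.12, adjusted p = 0.020) and the vitrin gene Vit at -0.57 (SE 0.11, adjusted p = 0.028). Myocd, the myocardin coactivator of smooth muscle genes, was at -0.53 (SE 0.10, adjusted p = 0.019), and Ptgfr, the receptor for prostaglandin F2 alpha, at -0.56 (SE 0.12, adjusted p = 0.041). Wfdc1 was at -0.57 (SE 0.098, adjusted p = 0.0095) and Susd2 at -0.57 (SE 0.098, adjusted p = 0.0095). Of the genes named in this part, only Susd2 also passed against WT alone (adjusted p = 0.022), and none passed against ApcKO alone. None of them was run through the alternatives. Mt2, with an adjusted p of 0.046 in the same comparison, passed under 6 of 35.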
